A study of Mus musculus with 2 samples.

How the data were processed

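Long-read RNA sequencing of gastrocnemius muscle was analysed from 2 libraries, which per the labels are biological replicates 1 and 2 of male B6CASTF1/J mice aged 18 to 20 months, each made from 2 µg of total RNA with SIRV and ERCC (Ambion mix 1) spike-ins. The labels name separate biosamples. Whether each stands for 1 mouse or for pooled tissue, and whether the libraries shared a sequencing run, are not given in the sources used here. Replicate numbers were taken from the labels.

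The deposited values were raw counts of reads per transcript model, 1 table per library, with models of 0 reads not listed. Per the README files deposited with the samples, the authors derived the counts from a filtered alignment to mm10 with the GENCODE M21 annotation. Per the source field of the deposited annotations, models were named by TALON, which sorts reads into known transcripts, incomplete splice matches (ISM), unannotated combinations of known splice sites (NIC), models with an unannotated splice site (NNC), and genomic, antisense and intergenic models. The aligner, the sequencing platform, software versions and any filter on models are not given in the sources used here. Per the file headers, each table also gave exon number and length, and the deposited annotation of each library gave exon coordinates, used here as 1-based positions on mm10. SIRV reads and the read sequences were not analysed here, and neither was a genome sequence, so allele of origin was not assigned.

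Counts were summed per annotated gene over all read classes, and levels were expressed as counts per 1000000 reads in the table (CPM). Shares of reads carry exact 95% Clopper-Pearson intervals. A count of 0 was read against a floor of 3 reads per library, equal to 1.99 CPM in replicate 1 and 2.56 CPM in replicate 2, and folds against 0 are lower bounds set at that floor. Intervals and floors cover counting error only, because copies of the same molecule cannot be told from separate molecules. Models with 1 read made up 59.8% of the 85723 models of replicate 1 and 61.5% of the 86916 models of replicate 2. Models of the 2 libraries were matched by intron chain, since the identifiers of unannotated models are specific to a library. Unannotated single-exon models have no intron chain and were pooled per gene for isoform shares.

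There was no comparison between groups. Genes with at least 10 reads over both libraries were compared between the libraries by a two-sided Fisher's exact test of the gene's reads against all other reads, with Benjamini-Hochberg adjustment, and called at an adjusted p below 0.05 and at least 2-fold. Log2 ratios are replicate 2 over replicate 1 on the log2(CPM + 1) scale, which understates the ratio of low genes. This test compares these libraries, not conditions, and the differences have no replicate check. The dominant transcript of each gene with at least 20 reads in each library was tested by Fisher's exact test against the gene's other transcripts. The biological coefficient of variation came from edgeR (4.0.16) with an intercept-only design and TMM scaling, and size factors for an alternative from DESeq2 (1.42.0) in R 4.3.3. The other steps ran in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6.

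The 22 gene lists were fixed before the data were examined, as were the tests and most alternatives. They cover fast and slow contractile genes, developmental muscle genes, glycolysis, nuclear and mitochondrial genes of respiration, calcium handling, the neuromuscular junction and denervation, atrophy and ageing, the circadian clock, stress and immediate-early genes, genes with regulated splicing, giant genes, and markers of fibroblasts, tendon, adipocytes, endothelium, smooth muscle and pericytes, immune cells, blood, Schwann cells and satellite cells. Some genes stand in several lists. Single-gene results of 2 list members are not reported here, while the list values include them where they were tested. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and its median CPM among 10000 random lists of genes with reads. List counts are given over all genes tested and adjusted over the list alone. Named genes are the members of these lists, the 25 most read genes, the 10 highest and 10 lowest called log2 ratios with a mean of at least 20 CPM, the 15 lowest adjusted p of isoform usage, the 15 most read unannotated models found in both libraries, the 15 genes with at least 100 reads in each library and the lowest dominant share, Xist and 4 Y-linked genes, and the 10 most read non-coding genes. Genes named outside this rule are said to be so where they appear.

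Alternatives changed the scaling (TMM or DESeq2), the read minimum, the fold minimum (4), the pseudocount (5), the classes of reads counted, the depth of the deeper library, the choice of dominant transcript, the rule for shared models, and the library left out. The comparison of single exons, and ratios centred on genes of like transcript length (20 bins), were added after seeing the data. For each exon that annotated transcripts variously keep or skip, reads of models spanning it were counted as keeping or skipping it, and exons with at least 50 such reads in each library were compared by Fisher's exact test.

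The gene, isoform and list comparisons between the libraries were tested on simulated data. These data held sampling error only, without the further variation seen between the libraries. The rates for unchanged genes and lists therefore cover counting error alone. Exon counting was checked on 3 hand-made models. List levels, centring on length and the exon test were not simulated. In counts drawn for 9029 genes, 57.7% of true 3-fold changes between the libraries and 82.8% of 6-fold changes were called, or 88.7% and 100% among genes with at least 50 reads, and 0.0113% of unchanged genes were called. For isoform usage over 4535 genes, 48.5% of changes of 30 points were called and 0.115% of unchanged genes. For list shifts, a list of 12 genes moved by a log2 ratio of 2 reached percentile 100, and 3 of 100 unchanged lists fell outside the central 95%. Spike-in RNAs were counted in the totals but not tested as genes.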

Results

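Full-length cDNA reads were counted per transcript in the gastrocnemius, the large calf muscle, of male mice aged 18 to 20 months from a first-generation cross of C57BL/6J and CAST/EiJ (B6CASTF1/J). There was 1 group of 2 libraries, labelled as biological replicates 1 and 2 and each made from 2 µg of RNA, and no second condition, so the questions were what this muscle transcribes, in which isoforms, and how far the 2 libraries differed. Replicate 1 held 1509380 reads and replicate 2 held 1173233. Reads fell on 14900 annotated genes, 11907 of them in both libraries. With 1 group there was no comparison across replicates to test. Levels are therefore given as the mean with its SD (n = 2), and tests on reads compared these libraries, not conditions.

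The library was dominated by the machinery of fast, glycolytic fibres. Atp2a1, the calcium pump of the fast sarcoplasmic reticulum, took 16.3% ± 1.66 of all reads (SD, n = 2), followed by Ckm, muscle creatine kinase, with 5.78% ± 1.13, Acta1, skeletal alpha-actin, with 4.75% ± 0.725, and Myh4, the myosin heavy chain of the fastest (type 2B) fibres, with 2.62% ± 0.455. Tnnc2, fast troponin C, and Tpm1, alpha-tropomyosin, came next with 2.14% ± 0.919 and 1.86% ± 0.809. The 25 most read genes, among them Actn3, Aldoa, Myl1, Slc25a4, Mybpc2, Mylpf, Ldha, Eno3 and Ak1, held 46.5% of the reads of replicate 1 and 41.5% of those of replicate 2. Among the gene groups fixed in advance, the fast-fibre contractile genes had a median of 5564 ± 1358 counts per 1000000 reads (CPM), the glycolytic enzymes 2126 ± 982, the calcium-handling genes 789 ± 71.5, the nuclear genes of oxidative phosphorylation 644 ± 12.2, and the mitochondrially encoded genes 103 ± 36.7. Genes of the mitochondrial genome together held 0.213% of the reads of replicate 1 and 0.287% of those of replicate 2. Whether their recovery matched that of nuclear genes was not tested, so these levels do not compare mitochondrial with nuclear transcription. Across 9032 genes with at least 10 reads over both libraries, log2 levels correlated with Pearson's r = 0.903 and Spearman's rho = 0.889. These are correlations across genes, which are not independent replicates. The libraries differed by far more than sampling noise (chi-square per degree of freedom 13.3), with a biological coefficient of variation of 0.306 by edgeR.

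The libraries differed most in fibre type. Myh4 gave 94.5% of the myosin heavy chain reads of replicate 1 and 74.0% of those of replicate 2. In replicate 2 the slower isoforms took larger shares: Myh1 (type 2X fibres) 14.3% against 4.57%, Myh2 (type 2A) 5.78% against 0.611%, and Myh7, the slow type 1 myosin, 5.85% against 0.324%. The Myh4 level itself, at 22961 and 29395 CPM, had no call, and its direction depended on the scale, with a log2 ratio of 0.36 on total reads and -0.30 after centring on genes of like transcript length. These shares rest on 36680 and 46618 reads. The exact 95% Clopper-Pearson interval of the Myh7 share ran from 0.269% to 0.388% in replicate 1 and from 5.64% to 6.07% in replicate 2. Counting only reads of annotated transcripts lowered the mean Myh4 share from 84.2% to 64.3% and raised that of Myh1 from 9.43% to 22.9% and that of Myh7 from 3.09% to 7.81%.

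**Figure D1:**
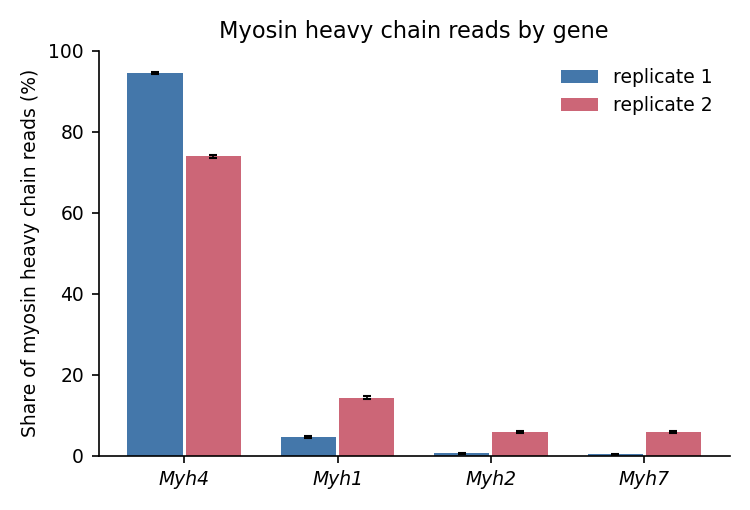
Share of sarcomeric myosin heavy chain reads (%, vertical axis) taken by Myh4, Myh1, Myh2 and Myh7 in each library; error bars are exact 95% Clopper-Pearson intervals. Myh4 stood at 94.5% in replicate 1 and 74.0% in replicate 2, and Myh7 at 0.324% and 5.85%.

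Every gene of the slow-fibre list was higher in replicate 2. All 12 tested members passed the threshold (12 higher, 0 lower, 0 without a call; 12 when adjusted over the list alone), with a median log2 ratio of 3.23 that lay at percentile 100 of 10000 expression-matched random lists. With Myh7b, the only member without reads in replicate 1, set at its bound, the median was 3.21. Myh7 (chromosome 14, 54970684 to 54994626) had 119 reads in replicate 1 and 2729 in replicate 2. Csrp3, the muscle LIM protein, had 7 and 184, and Tnnt1, slow troponin T, had 111 and 827 (log2 ratio 3.24). Atp2a2, the slow and cardiac calcium pump, had 95 and 688, and Ankrd2, a stretch-responsive protein of slow fibres, had 18 and 155. The 12 calls held under each alternative scaling and filter in which the genes could be tested (9 of 9 with annotated transcripts only).

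The fast-fibre list moved the other way, with a median log2 ratio of -0.75 at percentile 0. Of its 14 members 2 were higher in replicate 2, 4 lower and 8 without a call, among them Myh4 and Atp2a1 (0.21 on total reads), with the same counts when adjusted over the list alone. The higher genes were Myh2 (log2 ratio 3.94) and Myh1 (2.35). The lower ones were Pvalb, the calcium buffer parvalbumin (-1.49), Mylpf and Myl1, fast myosin light chains (-1.47 and -1.13), and Tnni2, fast troponin I (-1.38). Once ratios were centred on genes of like transcript length, a step added after seeing the data, Myl1 and Tnni2 lost their calls, with -0.72 and -0.85.

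Stress genes were also higher in replicate 2. Of 9 tested immediate-early and heat-shock genes 7 were higher and 2 had no call (8 higher when adjusted over the list alone), with a median log2 ratio of 1.54 at percentile 100. Hspa1a, an inducible Hsp70 chaperone, had 18 reads in replicate 1 and 182 in replicate 2, and its near-identical neighbour Hspa1b had 34 and 149, so that the split between these copies is uncertain. Atf3, a stress-induced transcription factor, had 3 and 58, and Fos 1 and 22. Jun, Junb and Dnajb1 were higher as well, at log2 ratios of 1.34, 1.23 and 1.27; Dnajb1 lost its call after centring on length (0.97).

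Energy metabolism differed less. In the glycolysis list 1 of 13 genes was higher, none was lower and 12 had no call (1 higher when adjusted over the list alone). The exception was Hk2, hexokinase 2, with a log2 ratio of 1.30 (0.65, no call, after centring on length). The list median of -0.42 lay at percentile 1.00, below the central 95% of random lists. Gapdh, at 40 and 23 reads, was far below the other enzymes, and its many processed pseudogenes make its count uncertain. Of 16 nuclear genes of oxidative phosphorylation 0 were higher, 2 were lower (Cox8b and, at -1.05, Ndufa4, electron transport subunits) and 14 had no call, also when adjusted over the list alone, and the median of -0.03 was within the random range. Both lost their calls without incomplete and genomic reads, Cox8b by slipping just under 2-fold (-0.98) and Ndufa4 at -0.71, and after centring on length (-0.47 and -0.53). Of 10 mitochondrially encoded genes mt-Nd5, a complex I subunit, was higher (log2 ratio 1.61) and 9 had no call (1 higher over the list alone), with a median of 0.38, which after centring on length was 0.71, above the random range.

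Calcium-handling genes had a median log2 ratio of 0.08, within the random range. Over the 11 with a length the median was -0.45, and -0.35 after centring on length, both below the random range. Of 13 tested, Pvalb and Mrln, which encodes the calcium pump inhibitor myoregulin (-1.25), were lower and 11 had no call (0 higher and 2 lower over the list alone); Mrln lost its call after centring on length (-0.72). Sln, which encodes the pump regulator sarcolipin, had 0 and 2 reads. In the neuromuscular junction and denervation list Myog, a myogenic transcription factor (-1.30), and Gadd45a (-2.10) were lower and 7 of 9 had no call (2 lower over the list alone; median -0.03). Gadd45a, at 16 and 2 reads, lost its call without the read minimum and with the deeper library thinned (-2.05). The denervation-responsive Ncam1 and Runx1 had at most 1 read in a library, and Chrng had none. In the atrophy and ageing list the metallothionein gene Mt1 was lower, with 32 reads in replicate 1 and 0 in replicate 2 (at least 8.29-fold lower), and 8 of 9 genes had no call. Adjusted over the list alone, 2 were higher and 1 lower. The ubiquitin ligases Fbxo32 and Trim63 had log2 ratios of -0.09 and -0.73. The list median was -0.09, and -0.71 after centring on length, below the random range. Cdkn2a had no reads. In the circadian list Clock (1.68) and Cry1 (1.02) were higher, Per1 (-1.39) was lower and 6 of 9 had no call, with the same counts over the list alone and a median of 0.58 inside the random range; Cry1 lost its call under TMM scaling (0.83) and after centring on length (0.73), Clock after centring (0.92) and with annotated transcripts only (1.44), and Per1, at 26 and 7 reads, without the read minimum and with the deeper library thinned (-1.15). Among 6 tested developmental genes Myh3, the embryonic myosin, was higher with 0 and 14 reads (at least 6.0-fold), Actc1, cardiac alpha-actin, and Myog were lower, and 3 had no call, with the same counts over the list alone and a median of -0.23.

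Markers of other cell types differed in the vessel wall. Of 8 tested endothelial genes 3 were higher in replicate 2, Kdr and Tek, which encode growth-factor receptors of endothelium, and Cldn5, a tight-junction claudin (log2 ratios 1.98, 1.61 and 1.37), and 5 had no call. Of 5 smooth-muscle and pericyte genes 3 were higher, namely Myh11, Tagln and Rgs5 (1.78, 1.60 and 1.02), and 2 had no call. Both counts were the same over the list alone, and the list medians of 0.91 and 1.02 lay at percentiles 98.7 and 98.4. Blood and immune markers lay below the random range, with medians of -0.80 and -0.64 at percentiles 0.44 and 1.47. None of 4 globin genes was called, also over the list alone, and among 5 immune genes Cd74, the class II invariant chain, was lower (-1.19), also over the list alone; it lost its call with the deeper library thinned (-1.07) and after centring on length (-0.88). None of 11 fibroblast and matrix genes was called (median 0.06; Col3a1 346 and 288 reads, Dcn 365 and 295), nor any of 5 tendon genes (median 0.29) or the only tested satellite cell marker, Cdh15 (-0.58). All 3 groups gave 0 calls over the list alone as well. Lep, which encodes leptin, was the only called member of 7 adipocyte genes, at 2.19 (list median 0.00), and Mbp, a myelin gene, the only called member of 3 Schwann cell genes, at 1.14 (median 0.94); each list gave 1 call over the list alone. Tek, Rgs5 and Mbp lost their calls under TMM scaling (1.44, 0.83 and 0.95) and Lep with annotated transcripts only (1.46). The Schwann cell median was 1.08 after centring on length, above the random range, and the blood, immune and smooth-muscle medians moved inside the random range after centring on length (-0.27, -0.50 and 0.52).

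**Figure D2:**
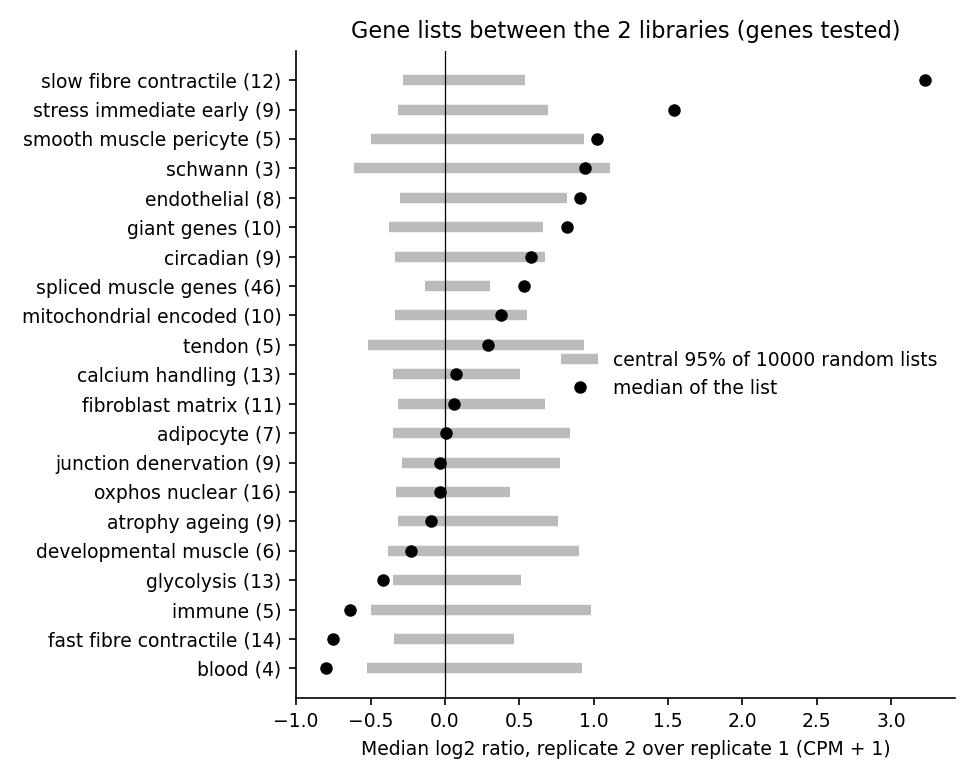
Median log2 ratio of replicate 2 over replicate 1 (CPM + 1, horizontal axis) for each gene list with at least 3 tested genes; points are list medians, grey bars the central 95% of 10000 random lists matched on expression, and numbers in brackets the genes tested. The slow-fibre list at 3.23 and the stress list at 1.54 lay above their bars, and the fast-fibre list at -0.75 lay below.

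Among other single genes Xirp1, Otud1 and Fhl1 were far higher in replicate 2, and Slc25a25, Mybph and Gadd45g lower. Xirp1, an actin-binding protein of muscle attachment sites, had 28 reads in replicate 1 and 909 in replicate 2 (log2 ratio 5.31; adjusted p = 5.57e-278, Fisher's exact test). Otud1, a deubiquitinase, had 33 and 636, and Fhl1, a LIM-domain protein of the sarcomere, had 144 and 1146. Topbp1 headed the list at 5.65, but lost its call without incomplete and genomic reads (0.86). The lower genes were Slc25a25, a mitochondrial ATP-magnesium carrier (622 and 94 reads, -2.35), Mybph, myosin-binding protein H (389 and 76, -1.98), Gadd45g, a growth-arrest gene (345 and 66, -2.00), Cebpd, a transcription factor (106 and 22, -1.85), Pnck, a calmodulin-dependent kinase (62 and 9, -2.28; no call with annotated transcripts only, -1.61), and Actc1 (55 and 5, -2.83). Cfap77, a cilium gene read only as an unspliced model, had 164 and 0 reads, at least 42.5-fold lower. The processed pseudogenes Gm6829 (209 and 0), Gm12033 (1180 and 142) and Amd-ps3 (70 and 10) were lower too, but share sequence with their parent genes, so that their counts are uncertain.

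In all, 744 of 9032 genes were at least 2-fold higher in replicate 2 and 184 lower at an adjusted p below 0.05 by Fisher's exact test, and 1932 had such a p at any fold. Thus 80.2% of the calls were higher in replicate 2. The median log2 ratio of all tested genes was 0.19 on total reads, and TMM scaling, which shifts all ratios by -0.19, gave 446 higher and 376 lower (54.3% higher). Centring on transcript length, added after seeing the data, left 347 higher and 129 lower of 8625 genes.

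Longer transcripts had higher ratios. The log2 ratio of replicate 2 over replicate 1 correlated with the length of the most read annotated transcript at Spearman's rho = 0.481 across 8625 genes. The median was -0.54 for transcripts of up to 500 nt, -0.13 between 1000 and 2000 nt and 0.69 above 5000 nt. ERCC spike-in RNAs, which carry no muscle sequence, took 2.71% of the reads of replicate 1 and 0.590% of those of replicate 2.

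**Figure D3:**
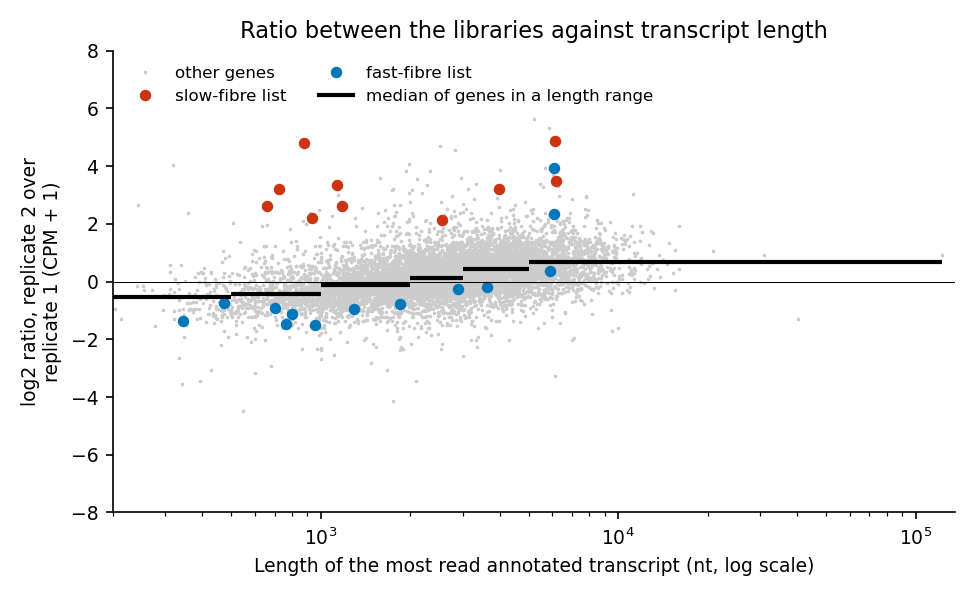
Log2 ratio of replicate 2 over replicate 1 (CPM + 1, vertical axis) against transcript length (nt, log scale) for each tested gene with a length. Black lines are medians per length range, red points the slow-fibre list and blue points the fast-fibre list. Medians ran from -0.54 for the shortest to 0.69 for the longest range. All 10 slow-fibre genes with a length lay above the median of their range.

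Most muscle genes were read mainly as 1 transcript, the same in both libraries. Tnnc2-201 gave 97.4% ± 0.0592 of the Tnnc2 reads (SD, n = 2), Mylpf-201, from the fast regulatory light chain gene, 96.0% ± 0.133, Tpm1-205 95.9% ± 0.458, and Ckm-203 95.4% ± 1.88. Myl1, whose alternative starts encode the long and short essential light chains, split into Myl1-202 with 64.5% ± 0.537 and Myl1-201 with 15.5% ± 0.203. Eno3, muscle enolase, was divided between Eno3-201 (52.0% ± 1.92) and Eno3-202 (25.9% ± 1.05). Across 4657 genes with at least 20 reads in each library, the transcript dominant in replicate 1 took a median of 78.4% of the reads of replicate 2, 76.0% for the reverse choice, and 92.5% of genes had the same dominant transcript in both. Some genes had no dominant transcript. In Mbnl1, a splicing factor, and Nrap, a thin-filament chaperone, the transcript with the most reads over both libraries took at most 16.5% and 17.7% in either. The kinesin-receptor gene Ktn1, the phosphodiesterase anchor Pde4dip, the translation factor Eif4g1, and Ubap2l, Bag6, Clip1, Sema6c and Rapgef1 likewise had at most 17.9% in their most read transcript. In Neb, Flnc, Tsc2 and the long non-coding RNA 2310065F04Rik the most read entry was not a full isoform. In Neb it was the pool of unannotated single-exon models (at most 4.90%), the most read of them genomic and of 615 nt. In the others it was an incomplete splice match (at most 12.3%, 9.68% and 17.9%). The low shares of these genes therefore do not count isoforms.

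The clearest isoform differences lay in Myl12a, Rcan1 and Tsc22d3. Myl12a-206, from a non-sarcomeric regulatory light chain gene, took 78.6% of Myl12a reads in replicate 1 and 31.8% in replicate 2 (adjusted p = 1.82e-29, Fisher's exact test). Rcan1-201, from the calcineurin regulator gene, was at 55.0% and 89.6% (adjusted p = 4.29e-25, Fisher's exact test), and Tsc22d3-201, from the glucocorticoid-induced leucine zipper gene, at 79.3% and 53.6% (adjusted p = 4.18e-15, Fisher's exact test). Among 4535 genes tested 120 passed, 41 of them by at least 20 points, and 479 had an unadjusted p below 0.05. In the list of genes known for regulated splicing in muscle 10 of 44 passed, 16 when adjusted over the list alone, among them Mybpc1, slow myosin-binding protein C (Mybpc1-202 at 57.8% and 40.3%), Fhl1 (Fhl1-204 at 68.1% and 86.5%) and Tpm3, slow tropomyosin (Tpm3-205 at 69.4% and 87.5%). Without incomplete (ISM) and genomic reads only 44 genes passed, 31 of them among the 120. Pvalb, Slc25a4, Ckm, Des, Atp2a1 and Mybpc2 then turned direction, and Acta1, Cacna1s and Tnni2 lost their calls. In Aldoa, Trdn and Ehbp1l1 the dominant model was itself an ISM, so that this setting puts another transcript in its place and does not test the difference. In Pvalb, for example, Pvalb-202 stood at 74.3% and 52.6% and the pooled unannotated single-exon models at 13.0% and 37.9% of its reads.

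Exon shares in the reads of sarcomere genes differed between the libraries. These shares are averages over all fibres of a library. A different mix of fibres and different splicing within fibres therefore cannot be told apart here. Tnnt3, fast troponin T, carries a pair of mutually exclusive 41-nt exons on chromosome 7. The exon at 142513665 to 142513705 was kept in 93.0% of spanning reads in replicate 1 and 68.9% in replicate 2, and that at 142514326 to 142514366 in 6.60% and 30.9% (adjusted p = 5.55e-96, Fisher's exact test). In Neb, which encodes the thin-filament ruler nebulin, 10 exons were kept more often in replicate 2. These exons lie between 52150537 and 52165277, with 150 to 170 spanning reads in replicate 1 and 234 to 279 in replicate 2. A read can span several of them, so they are not 10 independent results. The greatest difference was the 93-nt exon at 52150537 to 52150629 on chromosome 2, at 11.2% and 45.5%. A 59-nt exon of Mybpc1 (chromosome 10, 88521277 to 88521335) was kept in 6.99% and 32.6%, and a 105-nt exon of Nrap (chromosome 19, 56374364 to 56374468) in 86.1% and 60.1%. A 79-nt exon of Tpm3 (chromosome 3, 90091013 to 90091091) stood at 76.3% and 95.3%. Further exons of Mybpc1, Tpm3 and Mbnl2, a splicing factor, passed with differences of at most 10.6 points. Regulated exons of Dnm2, Mef2a and Mef2c had no call. Dnm2, dynamin 2, kept its 30-nt exon (chromosome 9, 21487047 to 21487076) in 49.1% and 49.4% of reads. The transcription factor genes Mef2a and Mef2c kept theirs at 67268067 to 67268204 on chromosome 7 in 48.3% and 47.5%, and at 83625265 to 83625408 on chromosome 13 in 25.7% and 25.6%. The adult 42-nt exon of Atp2a1 (chromosome 7, 126446545 to 126446586) was kept in 99.9% and 99.8%, a gap of -0.170 points that passed the test at this depth. This exon comparison was added after seeing the data. It covered 3296 exons that annotated transcripts variously keep or skip, with at least 50 spanning reads in each library, of which 33 passed and 132 had an unadjusted p below 0.05. In the regulated-splicing list 21 of 192 exons in 37 genes passed, the 10 Neb exons among them, and 22 when adjusted over the list alone.

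Annotated transcripts held 61.3% ± 3.53 of all reads (SD, n = 2) and incomplete splice matches (ISM) 9.45% ± 0.409. Unannotated combinations of known splice sites (NIC) held 4.44% ± 0.631 and models with an unannotated splice site (NNC) 19.7% ± 2.35. Genomic (unspliced) reads held 2.34% ± 0.0791, antisense reads 2.49% ± 1.00 and intergenic reads 0.279% ± 0.0296. Atp2a1 alone gave 80.6% of the NNC reads of replicate 1 and 79.6% of those of replicate 2, and without it the class fell to 4.09% and 5.25%.

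**Figure D4:**
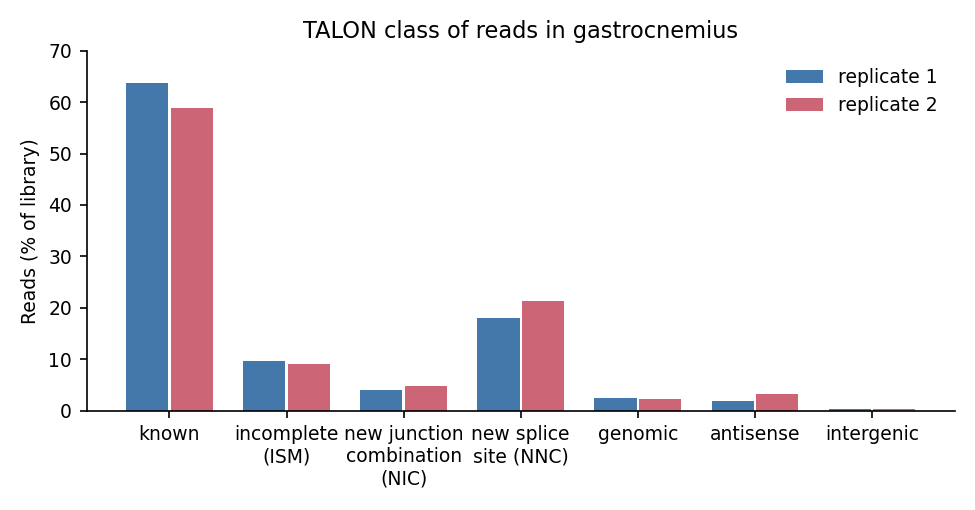
Share of all reads (%, vertical axis) in each TALON class of transcript model for both libraries; bars are single libraries without error bars. Known transcripts took 63.8% in replicate 1 and 58.8% in replicate 2, and models with an unannotated splice site 18.0% and 21.3%.

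The most read model of the whole dataset was unannotated. It belonged to Atp2a1 (chromosome 7, 126445858 to 126463108, minus strand), held 217244 reads in replicate 1 and 196261 in replicate 2, and made up 95.4% ± 0.388 of the Atp2a1 reads (SD, n = 2). Compared with Atp2a1-201 it lengthened exon 1 by 26 bases (126462779 to 126462804) and left out exon 2, of 18 bases (126462500 to 126462517), so that an intron ran from 126462188 to 126462778. Exon 2 was skipped by 423081 spanning reads and kept by 1. Myh4 had an unannotated intron from 67237834 to 67238030 on chromosome 11, just upstream of its annotated start, in a model with 34.8% ± 0.596 of its reads. Bin1, which shapes the T-tubule membrane, was read as an unannotated model in 62.1% ± 3.85 of reads, and Tnni2 in 55.3% ± 6.88. In the Tnni2 model an intron ran over a 7-base exon that all 7863 spanning reads skipped. In the Tnnt3 model named below, an intron ran over a 14-base exon that 99.9% of spanning reads skipped. Both models may be alignment artifacts at very short exons, as taken up later for Atp2a1, which was not tested for them. Oaz1 and Oaz2, the antizyme genes decoded by ribosomal frameshifting, were read without 1 annotated intron in 96.1% ± 0.112 and 93.5% ± 0.502. In each gene that intron is a gap of only a few bases in the annotation. The intron chains of the Oaz1 and Oaz2 models differed from the nearest annotated transcript by this gap alone. These models are therefore not evidence of a retained intron or a new isoform. Other unannotated models with many reads were those of Tmed2 (92.9% ± 0.457), Vdac3 (89.7% ± 1.54), Phkb (78.4% ± 2.98), Mknk2 (55.6% ± 6.48), Usp47 (53.0% and 49.0%), Srl (47.6% ± 4.95), Ndrg2 (42.9% ± 4.11) and Tnnt3 (16.2% ± 3.78). In all, 4305 unannotated intron chains in 2234 genes had at least 2 reads in each library and held 89.7% and 88.3% of the reads of such models.

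**Figure D5:**
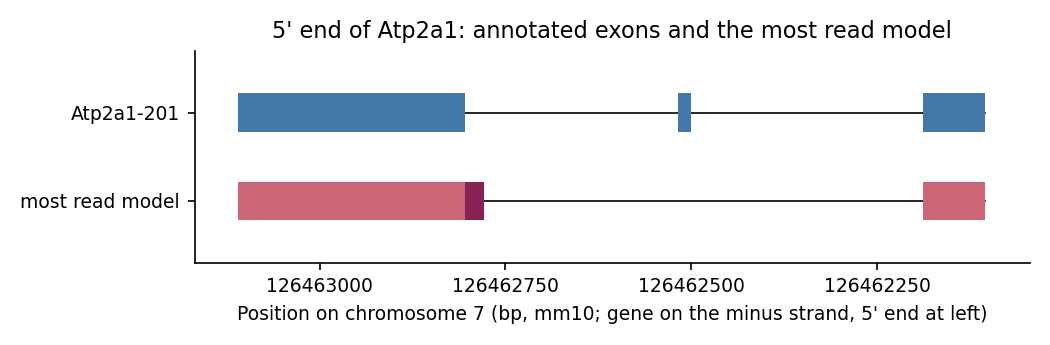
The 5′ end of Atp2a1 on chromosome 7 (position in bp, mm10, minus strand with the 5′ end at left): exons 1 to 3 of the annotated Atp2a1-201 above, and of the most read model below. The darker block marks the 26 added bases, and the 18-base exon 2 is missing from the model.

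Several of the longest muscle genes were read in pieces. Ryr1, the calcium release channel, had 94.5% of its reads as ISM in replicate 1 and 92.9% in replicate 2, Neb 69.4% and 60.1%, and Ttn, titin, 58.0% and 53.6%. Cacna1s, a calcium channel subunit, instead had 59.1% and 73.5% of its reads as annotated transcripts and 36.7% and 21.5% as ISM, and Plec had 19.9% and 27.7% as ISM. Dmd, dystrophin, had only 8 and 12 reads, and Syne1 9 in each. The ISM share of a gene correlated with transcript length at Spearman's rho = 0.329 across 5194 genes in replicate 1 and 0.328 across 4995 in replicate 2. It had a median of 1.25% and 0.602% for transcripts of up to 1000 nt, and of 12.1% and 11.1% above 6000 nt. Of the 10 giant genes tested between the libraries Plec, plectin, was higher in replicate 2 (log2 ratio 1.34) and 9 had no call. The counts were the same over the list alone, and the median was 0.82 at percentile 99.3. Over the 7 with a length the median was 0.83 at percentile 98.5. After centring on length it was 0.26 at percentile 85.4, inside the random range. Plec lost its call after centring on length (0.58), and without incomplete and genomic reads only 5 and 12 of its reads were left, at a ratio of 1.42. The 46 regulated-splicing genes had 9 higher, 2 lower and 35 without a call, also over the list alone, with a median of 0.53 at percentile 100. After centring on length the median was 0.12 at percentile 98.6, over the 40 genes with a length.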

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

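Of the tests in this part, that on very short exons and that on the slope of the spike-in ratios against length were set before their results were seen, and all others, with the value without Tnni2, were chosen after. The design has 1 group, so no biological explanation of a difference between the libraries was tested.

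Several signals lay outside the measurements used for muscle genes and exceeded the 3 reads that a count of 0 allows. ERCC spike-ins had 40948 reads in replicate 1 and 6922 in replicate 2. Antisense models opposite the non-coding gene Gm26917 (chromosome 17, 39843013 to 39848035, minus strand) had 5854 and 11228 reads, or 0.388% and 0.957% of the libraries. Antisense models opposite Klhl31, a muscle gene of the kelch family (chromosome 9, 77655527 to 77660127, minus strand), had 3499 and 4208 reads. Opposite the non-coding gene Gm26825 (chromosome 5, 5781530 to 5781615, minus strand), replicate 1 had 963 reads and replicate 2 had 0. Models at loci between annotated genes had 4189 and 3676 reads. The 3 antisense loci were named after their values were seen.

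The slow-fibre genes were higher in replicate 2 by a median log2 ratio of 3.23. Recovery that depends on transcript length cannot be the whole cause, since after centring on genes of like length the median was still 3.04 and all 10 members with a length stayed at 1.94 or more. The same holds for a few genes taking most of the reads, since the median was 3.03 on TMM library sizes. Heart RNA was argued against by Myh6, the main myosin of the adult mouse heart, which gave 0.547% of the Myh6 and Myh7 reads of replicate 2 (exact Clopper-Pearson interval 0.306% to 0.900%). A piece of muscle with more slow fibres and a difference between the mice cannot be told apart here, because each library is the only one of its sample; Myh7 at 5.85% of myosin heavy chain reads in replicate 2 is predicted by either and may reflect where the calf was sampled.

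The Atp2a1 model without exon 2 may be an alignment artifact at an exon too short to be placed. In 22 other genes, 22 exons of at most 20 bases that every annotated transcript spanning them keeps were skipped by a median of 99.97% of spanning reads, with 15 of 22 skipped by over 50%, while the median for exons of 51 to 100 bases was 0%. That most skipping reads end at an unannotated splice site, also set in advance, held in 16 of 20 exons with such reads. It did not hold in their sum (40.3%), of which Tnni2 gave 7863 of 13081 reads (95.0% without it). All exons of at most 16 bases were skipped by over 50%, but those of 17 to 20 bases were mixed. Exons of Atp2a2 and Trdn, of 18 bases like exon 2 of Atp2a1, were skipped by only 7.68% and 0.619%. Those of Sugt1 (17 bases), Rnf185, Rnf5 and Ik (19) and Nap1l1 (20) were also kept by most reads. Those of Hacd1 (19) and of Suds3, Trim44 and Chmp1a (20) were mostly skipped. Like Tnni2, these genes and this split by size were chosen after their values were seen. The median over all 22 exons therefore does not decide the question at 18 bases. Splicing as the model draws it would change the coding length by 8 bases, which leaves a remainder of 2 on division by 3 and would shift the frame of nearly all transcripts of the most abundant muscle gene. A sequence difference of the CAST allele would give the model at most 50% of Atp2a1 reads where both alleles are read alike, so its 95.4% goes against this, and it stays open only because the share of each allele is unknown.

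Short transcripts and ERCC spike-ins were both lower in replicate 2. Length-dependent recovery as the cause of the trend among mouse genes stays open. Among 36 ERCC transcripts of 274 to 1994 nt the ratio correlated with length at Spearman's rho = 0.243 (permutation p = 0.153). Pearson's r with log2 length was smaller, at 0.0513 (permutation p = 0.763). The bound set in advance, a p of 0.05 or more for rho, was too strict to count against length-dependent recovery. Only 22.9% of 2000 sets of mouse genes of like lengths reached the rho of 0.329 needed. Length alone did not account for the spike-in level, because 36 of 36 ERCC transcripts were lower and their median log2 ratio stayed at -1.77 after centring on length (bootstrap 95% interval -1.93 to -1.65).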

How the results depend on the processing

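Centring on transcript length and leaving out 1 short exon were added after seeing the data, and all other alternatives were set before the data were examined. Of 838 alternative values 722 kept their direction and their side of the threshold or stayed within the spread between the libraries, and 47 of 69 named genes did so under every alternative run. Scaling moved the balance of calls: TMM gave 446 higher and 376 lower and DESeq2 444 and 384, all of the 184 lower genes being kept by both. At least 4-fold, 162 and 39 genes remained; annotated transcripts only gave 790 higher and 101 lower, 477 and 98 of them among the 744 and 184; centring on length gave 347 and 129, 332 and 105 of them among these. Left without incomplete and genomic reads, 44 genes differed in isoform usage, and the difference in dominant share (replicate 2 minus replicate 1, in points) turned to -0.0768 for Ckm, -0.106 for Slc25a4, 0.648 for Pvalb, 5.88 for Aldoa, 2.17 for Trdn, 0.0371 for Des, -0.407 for Atp2a1 and -0.0661 for Mybpc2; by construction this setting removes reads from the gene totals and, in Aldoa and Trdn, puts another transcript in place of a dominant ISM model, and no other cause was tested. It raised the median dominant share to 89.3%, against 76.3% and 82.0% at minimums of 10 and 50 reads. Picking and reading the dominant transcript in a single library gave 76.0% to 78.4%. Correlations moved with the filter, Pearson's r to 0.928 without one, 0.881 at 50 reads and 0.894 with annotated transcripts only, and Spearman's rho to 0.909, 0.830 and 0.878. Annotated transcripts only gave mean myosin shares of 64.3% for Myh4, 22.9% for Myh1 and 7.81% for Myh7, as this removes the unannotated Myh4 model. Models with at least 2 reads lowered ISM to 8.72% and genomic reads to 2.16%. Shared unannotated models numbered 9761 at 1 read, 1632 at 5 reads and 0 by identifier, which differs between libraries by construction. Leaving out a library in turn gave ranges of 58.8% to 63.8% for known reads, 9.16% to 9.74% for ISM, 4.00% to 4.89% for NIC, 18.0% to 21.3% for NNC, 2.28% to 2.39% for genomic and 1.79% to 3.20% for antisense reads. The ranges were 74.0% to 94.5% for Myh4, 4.57% to 14.3% for Myh1, 0.611% to 5.78% for Myh2, and 0.324% to 5.85% for Myh7. In level, 9 to 10 lists lay above the central 95% in a single library, and 8 in both. The ISM rho ran from 0.328 to 0.329. After centring on length the mitochondrially encoded (0.71), atrophy (-0.71) and Schwann (1.08) medians left the random range. That of calcium-handling genes was below it over the 11 with a length both before (-0.45) and after (-0.35). Of the giant genes 70% had a length. Over these 7 the median was above the random range before centring (0.83) and inside it after (0.26). Where no construction is named, the cause was not tested. Depth limits isoform calls, since 48.5% of simulated 30-point changes were found, and thinning the deeper library left 96 genes, 91 of them among the 120.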

Other observations

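All tests in this part come from comparisons set in advance, and values named outside the gene rule were chosen after they were seen. The Y-linked genes matched the male sex given in the labels. Ddx3y, an RNA helicase gene, had 97 reads in replicate 1 and 133 in replicate 2, Eif2s3y, a translation factor gene, 77 and 48, Uty 9 and 15, and Kdm5d 5 and 4, and Xist, the RNA of the inactive X chromosome, had no reads in either library. No Y-linked gene passed the threshold between the libraries.

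The 10 most read genes annotated as non-coding were led by Prr33. It is annotated as a long non-coding RNA on chromosome 7 (142491074 to 142506771), where it overlaps Tnnt3 on the opposite strand, and had 333 ± 38.4 CPM (SD, n = 2), a count that is uncertain where reads were assigned without strand. Nctc1, also on chromosome 7 (142544609 to 142558596), had 129 ± 6.64 CPM, and 2310065F04Rik on chromosome 11 (67112461 to 67120080), near the fast myosin genes, 152 ± 26.8. Of the 10, 1700020I14Rik was the only call, higher in replicate 2 with 264 and 458 reads (log2 ratio 1.15). Ndufb1-ps, 2900097C17Rik, Cct6a, Atcayos, Tmem134 and Gm20659 had ratios of -0.83, 0.57, -0.08, 0.01, -0.37 and -0.06. The annotation types Cct6a and Tmem134 as processed transcripts, and whether they code for protein was not examined here. Imprinted H19, a non-coding RNA of embryonic and regenerating muscle, had 58 and 85 reads without a call.

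Of the markers of muscle stem cells Pax7, at 1 read in each library, Myf5, at 1 and 0, and Vcam1, at 3 and 2, were at or under the floor of 3 reads, Calcr had none, and Cdh15 was above it with 43 and 22. Adipocyte genes were low as well, with Adipoq at 15 and 22 reads and Fabp4 at 59 and 46. The acetylcholine receptor genes Chrna1 and Chrne had 24 and 28, and 39 and 18 reads, without a call. The hypoxia-inducible growth factor gene Vegfa, at 89 and 222 reads (log2 ratio 1.67), and Ppargc1a, a regulator of mitochondrial biogenesis, at 19 and 43 (1.47), were both higher in replicate 2; Ppargc1a lost its call with only reads of known transcripts (1.27) and after centring on length (0.82).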
